A study of Mus musculus with 10 samples.

How the data were processed

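The libraries came from 10 mouse brains, 5 wildtype and 5 Abcc5 knockout, all FVB/NJ per the labels. The mice were killed with carbon dioxide, the brains were frozen at once, and libraries were made from polyadenylated RNA. The deposited table held counts per Ensembl gene and library, for which the authors name TopHat2 2.0.6, HTSeq, edgeR and limma as tools. What each tool did, its settings and the genome build are not given. It also held a log2 fold change (another unit) and an adjusted p-value per gene, both computed by the authors and deposited in damaged form. In 629 fold change cells (2.51%) and 8 p-value cells the number had been damaged, mostly by a lost decimal point, so only intact cells were read. A further 10 columns of values per library had also lost decimal points and were not used here. Deposited positions on chromosome 7 reach 152509964, past the last GRCm38.p6 gene end at 145324059, so positions were taken from the table alone.

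Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 14526 of 25050. Libraries were scaled by TMM (factors 0.982 to 1.01), and a quasi-likelihood model with genotype as its only term was tested for each gene, with Benjamini-Hochberg adjustment over all tested genes. Levels are CPM scaled by TMM, given as mean ± SD, and log2 CPM used a prior count of 2. The SE of a log2 fold change was derived from the F statistic. Total counts were 7731294 to 23588335 per library, and the common biological coefficient of variation was 0.071. Between replicates the chi-square per degree of freedom was 1.29 to 12.8, above counting error. Intervals on counts are 95% exact Poisson intervals and cover counting error only.

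Gene lists for ABCC5 substrates, cell states, cell types and brain regions (41 lists, 39 with at least 3 tested members) were tested by camera of limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation, and by fry. Calls near Abcc5 were compared with Fisher's exact test, two-sided, in a window of 10 Mb. The test, the samples, the lists, the named-gene rule and most alternatives were fixed before the data were examined. The rule named Abcc5, called members of a list (at most 30), the 10 called genes with the largest change in each direction with non-overlapping groups and a mean of at least 1 CPM, the 5 smallest p-values in each direction, the 2 members of each list with the smallest p and the 2 most expressed, and calls within 10 Mb of Abcc5.

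Alternatives fixed in advance were DESeq2 size factors, upper-quartile scaling, no low-count filter, at least 1 CPM in 5 libraries, the replicate number as a block, leaving out each library, limma-voom with and without sample weights, the Wald test of DESeq2 1.42.0, adjusted p thresholds of 0.01 and 0.1, a test against a 1.2-fold change, windows of 5 and 20 Mb, and the estimated correlation and fry. Alternatives chosen after seeing the data were the 7 libraries with at most 11479995 counts (the shallower libraries), depth class as a term, removal of each library's GC trend (14142 genes with a transcript GC in the reference), and an exact two-sided permutation test of each list's mean log2 CPM over 252 assignments. A sex covariate was planned for libraries of both sexes and not run, since all 10 had Y-linked counts (Ddx3y at least 686) and at most 6 counts of Xist. The method was tested on simulated data, where 84 of 100 genes changed 1.5-fold and 93 of 100 changed 2-fold were recovered, with 6 of 14304 unchanged genes called. The simulated genes were drawn independently, without an outlying library, a GC trend or correlation between genes, so these shares may not hold in the real data.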

Results

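RNA from brains of FVB/NJ mice was sequenced to compare animals labelled as knockouts of the transporter gene Abcc5 with wildtype animals. Each group had 5 libraries, named here by group and replicate, and the labels describe each as a whole brain. The deposited table held counts for 25050 genes, of which 14526 had enough counts to be tested. Total counts ran from 7731294 to 23588335 per library. Wildtype replicate 1 and knockout replicates 2 and 4 had at least 19795743 counts and are called the deeper libraries here, and the other 7 had at most 11479995. Knockout replicate 3 stood apart on the first principal component, which took 33.0% of the variance. That library almost lacked transcripts typical of the cerebellum, so its effect is given beside the results it changed. The edgeR p-values weigh the difference between the groups against the spread between libraries within a group. Camera compares the genes of a list with all others, and Fisher's test compares counts of genes.

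The first comparison asked how far the Abcc5 transcript itself differed. Abcc5 encodes an ATP-binding cassette transporter that moves organic anions out of cells. Its transcript level (ENSMUSG00000022822, chromosome 16, 20331376 to 20426467 in the coordinates of the deposited table, whose genome build is not named) was 311.1 ± 12.6 CPM in wildtype and 218.8 ± 5.95 CPM in knockout brains (SD, n = 5 each). This was a reduction of 29.7%, or a log2 fold change of -0.51 (SE 0.041), with an edgeR adjusted p of 6.35e-06. The lowest wildtype library had 299.2 CPM and the highest knockout library had 226.2 CPM. Among the deeper libraries, which hold 1 wildtype and 2 knockout brains, the log2 difference was -0.57, and among the other 7 it was -0.49. The table gives a single count per gene, so the exons that the remaining knockout reads came from are not known.

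**Figure D1:**
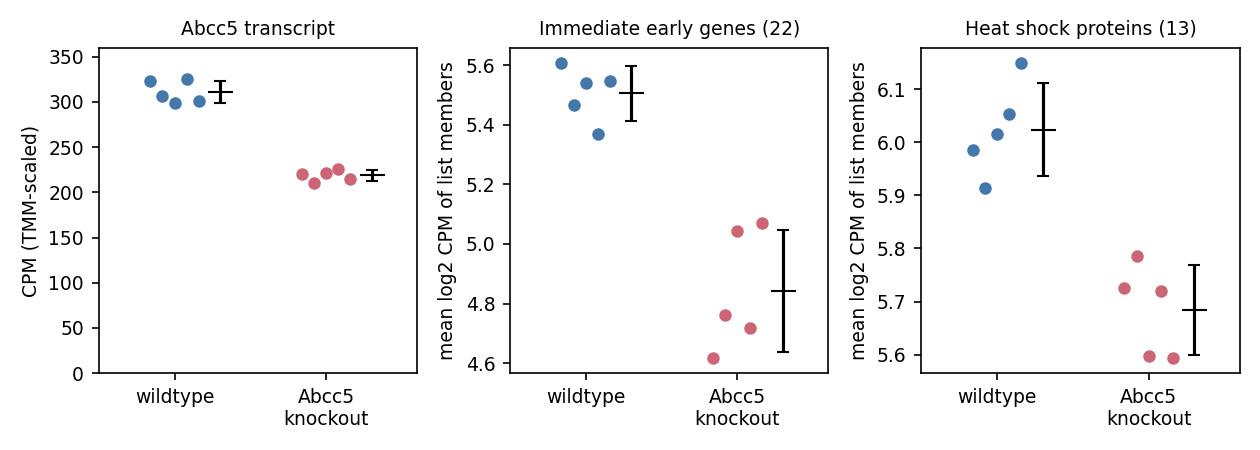
Abcc5 level (CPM, left) and mean log2 CPM of the immediate early genes (middle) and heat shock proteins (right) in each library (points), with the mean and SD of each group (n = 5). Neither Abcc5 nor the immediate early or heat shock scores overlapped between the groups.

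The comparison of all genes asked which transcripts changed in the knockout brain. Most of the changes were reductions. Genes that neurons switch on rapidly when stimulated, the immediate early genes, fell by up to about 3-fold, and several heat shock and endoplasmic reticulum chaperones fell with them. A smaller set rose, in which Alg1, a mannosyltransferase of protein glycosylation, and Cirbp, a cold-inducible RNA-binding protein, had the smallest p-values. By edgeR, 171 genes passed an adjusted p of 0.05, with 31 higher and 140 lower in knockout, and 170 remained when Abcc5 itself was set aside. An unadjusted p under 0.05 was reached by 2145 of the 14526 tested genes, the share to hold the list counts below against. The changes were mostly modest, with a median absolute log2 fold change of 0.358, and 38 genes changed over 1.5-fold, of which 35 were lower. In 163 of the 171 genes the groups did not overlap at all, which their small p-values alone make likely. Over all tested genes, non-overlap held for 4.19%, where chance gives 0.794%. The count depended on single libraries. It was 112, 88, 76 and 78 without wildtype replicates 2, 3, 4 and 5, and 105, 87 and 87 without knockout replicates 1, 2 and 4. Without knockout replicate 3 it was 341, which included all 171. With 1 library left out, the number higher ran from 8 to 93 and the number lower from 67 to 248. In the authors' deposited table, 111 genes had an intact adjusted p under 0.05, and 108 of these were among the 171.

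The immediate early genes gave the clearest change of any group. Of 22 tested members, 13 fell and none rose over all genes, 18 fell when adjusted over the list alone, and the median log2 fold change was -0.57. Egr2, a transcription factor, fell from 12.3 ± 1.40 to 4.37 ± 1.57 CPM (n = 5 each, log2 fold change -1.57, edgeR adjusted p 0.000151). Nr4a3, a nuclear receptor, fell from 59.9 ± 4.50 to 24.1 ± 4.22 CPM (edgeR adjusted p 5.17e-06). Arc, which acts in synaptic plasticity, fell from 205.4 ± 18.5 to 92.1 ± 14.9 CPM (edgeR adjusted p 5.17e-06). The AP-1 subunits Fos, Fosb and Fosl2 had log2 fold changes of -1.07, -1.12 and -0.99, and Nr4a1, Nr4a2 and the kinase Sik1 had -0.995, -0.55 and -0.82. The phosphatases Dusp1 and Dusp6 and the clock component Per1 also fell, with log2 fold changes of -0.60, -0.46 and -0.62. Egr1 passed in all 10 libraries (log2 fold change -0.60, edgeR adjusted p 0.0308). Its call was lost without wildtype replicates 1, 2, 3 or 5 or knockout replicates 1, 2 or 4, at adjusted p-values between 0.0548 and 0.0965. In the 7 shallower libraries alone, Fos, Fosb, Dusp1, Dusp6, Nr4a2 and Egr1 did not pass (edgeR adjusted p 0.0543 to 0.295). Homer1, a scaffold of the synapse, did not pass (log2 fold change -0.36, edgeR adjusted p 0.312).

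As a list, the immediate early genes had a camera adjusted p of 1.22e-62, and an adjusted p of 0.00824 with an estimated correlation. Their mean log2 CPM was 5.51 ± 0.092 in wildtype and 4.84 ± 0.204 in knockout (n = 5 each), without overlap. The two-sided exact permutation p was 0.00794, the smallest that 252 assignments can give, and 0.0516 after adjustment over the 39 lists. No list passed this test after adjustment, so the exact permutation p-values below are unadjusted unless stated. The difference was -0.87 among the deeper libraries and -0.57 among the other 7.

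**Figure D2:**
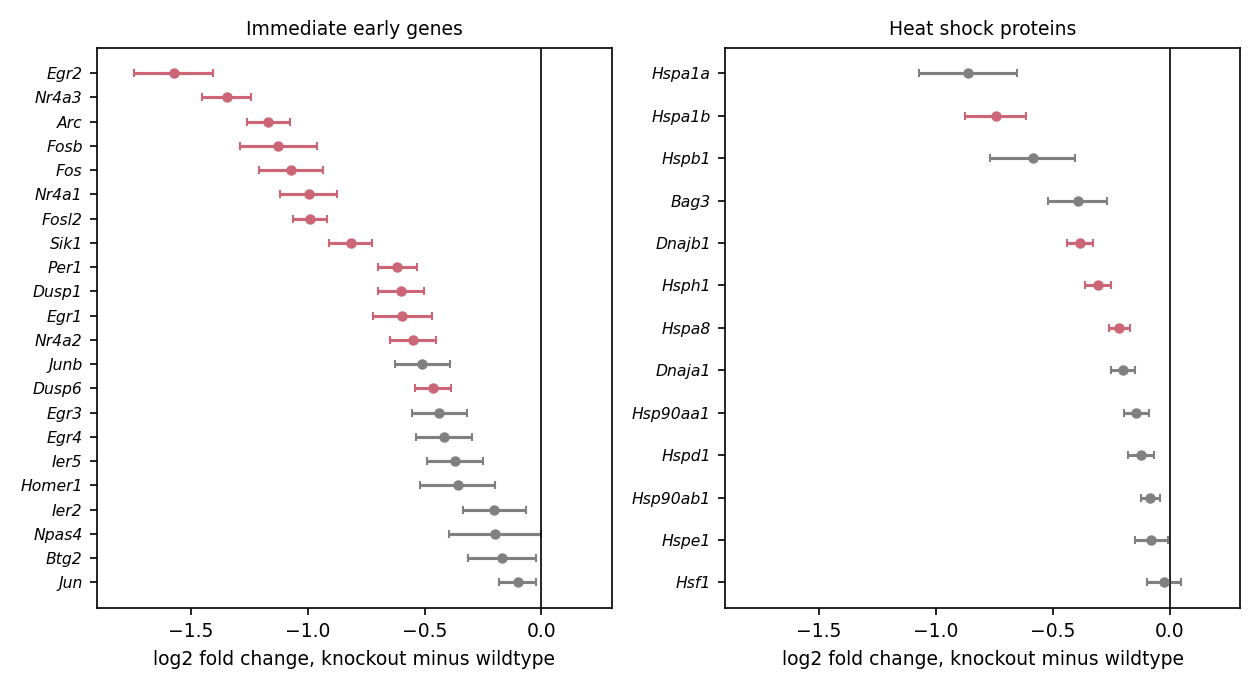
Log2 fold change (knockout minus wildtype) of each tested immediate early gene and heat shock protein gene, with bars for the SE (n = 5 per group) and red points for an edgeR adjusted p under 0.05. All 22 immediate early genes lay below 0, and 13 passed the threshold.

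Heat shock protein genes, which encode chaperones, also fell. Of 13 tested members, 4 fell and none rose over all genes, and 9 fell when adjusted over the list alone. Dnajb1 fell from 63.6 ± 5.07 to 48.8 ± 1.29 CPM (n = 5 each, log2 fold change -0.38, edgeR adjusted p 0.00247). Hspa1b had a log2 fold change of -0.74 (edgeR adjusted p 0.00968), although its reads cannot be cleanly parted from those of its near-identical paralog. Hsph1 and Hspa8 had log2 fold changes of -0.31 and -0.22. Hsph1 lost its call without wildtype replicates 3, 4 or 5 (edgeR adjusted p 0.0553, 0.0667 and 0.061). Hspa8 lost its call without wildtype replicates 3, 4 or 5 or knockout replicates 1, 2 or 4 (edgeR adjusted p 0.0558 to 0.112). In the 7 shallower libraries alone none of these 4 genes passed (edgeR adjusted p 0.0543 to 0.207). The abundant Hsp90ab1 and Hsp90aa1 had log2 fold changes of -0.083 and -0.14 and did not pass. The list had a median of -0.22, a camera adjusted p of 3.96e-13, and an adjusted p of 0.0213 with an estimated correlation, which was 0.0573 without knockout replicate 3. The mean log2 CPM differed by -0.34 (exact permutation p 0.00794), by -0.23 among the deeper libraries and by -0.39 among the others.

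In the list for the unfolded protein response and amino acid stress, 2 of 16 members fell, and 4 fell when adjusted over the list alone. Xbp1, a transcription factor of the unfolded protein response, fell from 98.1 ± 3.32 to 72.5 ± 5.86 CPM (n = 5 each, edgeR adjusted p 0.000515). Hspa5, the main chaperone of the endoplasmic reticulum, fell from 384.7 ± 28.0 to 274.8 ± 25.5 CPM (edgeR adjusted p 0.00128). Asns and Psat1, enzymes of amino acid synthesis, had log2 fold changes of 0.036 and 0.040. The list median was only -0.037 (-0.073 to -0.023 with 1 library left out), with a camera adjusted p of 0.00192 and an adjusted p of 0.13 with an estimated correlation. Its mean log2 CPM differed by -0.13 (exact permutation p 0.00794), by -0.16 in the deeper libraries and by -0.13 in the others.

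The lists of ribosomal protein genes and of genes encoded by the mitochondrial genome had medians slightly above 0 and passed by camera with the preset correlation. Of 24 ribosomal members, 13 rose when adjusted over the list alone. The ribosomal median was 0.13, with a camera adjusted p of 4.44e-11 and an adjusted p of 0.143 with an estimated correlation. Of 12 mitochondrial members 1 rose over all genes, mt-Nd5 of respiratory complex I (log2 fold change 0.25, edgeR adjusted p 0.0343), and 11 rose when adjusted over the list alone. The mitochondrial median was 0.18, with a camera adjusted p of 8.33e-09, an adjusted p of 0.312 with an estimated correlation and 0.111 by fry. The mean log2 CPM of the lists differed by 0.14 (exact permutation p 0.00794) and 0.18 (exact permutation p 0.0317). In the deeper libraries these differences were 0.095 and 0.15, and in the others 0.14 and 0.18. Knockout replicate 3 had the highest mitochondrial score, 11.68, and without it the median was 0.131 (camera adjusted p 6.21e-07). The score of knockout replicate 5, 11.29, lay within the wildtype range. The call of mt-Nd5 was lost without wildtype replicates 2, 3, 4 or 5 or knockout replicates 1, 2 or 4, at edgeR adjusted p-values of 0.0654 to 0.117. It also missed the threshold once the GC trend of each library was removed (adjusted p 0.0625).

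Outside these lists, Emp2, a membrane glycoprotein of the tetraspan family, fell from 28.0 ± 1.27 to 15.01 ± 1.10 CPM (n = 5 each, edgeR adjusted p 5.05e-06). Alg1 rose from 10.4 ± 0.872 to 19.7 ± 0.968 CPM (edgeR adjusted p 6.35e-06), and Cirbp rose from 56.3 ± 4.79 to 81.2 ± 3.58 CPM (edgeR adjusted p 0.000256). Emp2 and Alg1 lie on chromosome 16, as Abcc5 does. The pseudouridine synthase gene Trub2 and Zc3h6 rose, with log2 fold changes of 0.50 and 0.45. The death receptor gene Tnfrsf25 and the lipid metabolism gene Tm6sf2 fell, with log2 fold changes of -1.18 and -1.16, and in the 7 shallower libraries alone did not pass (edgeR adjusted p 0.0506 and 0.0654). The strand of counting is not given, so the reads of genes that overlap on opposite strands cannot be parted.

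ABCC5 is studied as a transporter of glutamate conjugates, so 10 lists on its known or related substrates were examined for a response. These genes showed little difference. By edgeR, 1 of their 188 tested genes passed over all genes, Slc38a2, a sodium-coupled transporter of glutamine and other neutral amino acids. It fell from 244.3 ± 15.7 to 197.8 ± 10.8 CPM (n = 5 each, log2 fold change -0.30, edgeR adjusted p 0.00891, and 0.109 in the 7 shallower libraries alone). At an unadjusted p under 0.05 there were 19 genes, 10 higher and 9 lower. DESeq2 and limma-voom called 1 each, and limma-voom with sample weights called 7. The median log2 fold changes were 0.0085 for glutamate transport, 0.025 for glutamate receptors, 0.0063 for glutamate, glutamine and GABA metabolism, -0.031 for N-acetylaspartylglutamate (NAAG) metabolism and 0.045 for ABC efflux transporters. They were 0.0021 for folate metabolism, -0.0034 for cyclic nucleotides, 0.059 for heme and iron, 0.059 for glutathione and -0.028 for purines. With 1 library left out, the medians of glutamate transport, of glutamate, glutamine and GABA metabolism, of folate metabolism and of cyclic nucleotides changed sign. Glutamate receptors then ran from 0.0080 to 0.051, NAAG metabolism from -0.049 to -0.0080 and ABC efflux transporters from 0.014 to 0.077. Heme and iron ran from 0.024 to 0.079, glutathione from 0.042 to 0.071 and purines from -0.042 to -0.019. None of the 10 lists passed by camera, with adjusted p-values from 0.0904 to 0.991, and adjusted over the list alone 1 gene fell in glutamate transport, 2 rose in heme and iron and 1 in glutathione.

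Within these lists, the glial glutamate transporter genes Slc1a2 and Slc1a3 had log2 fold changes of 0.093 and 0.041, and the cystine-glutamate exchanger gene Slc7a11 had -0.22 (edgeR adjusted p 0.197). Nat8l, which makes N-acetylaspartate, had -0.011, and the NAAG-related genes Naalad2 and Grm3 had -0.54 and 0.26, with edgeR adjusted p-values of 0.219 and 0.188. Hmox2, a heme oxygenase, and Gpx1, a glutathione peroxidase, had 0.20 and 0.22, with edgeR adjusted p-values of 0.0755 and 0.0991. The mean score of the NAAG list differed by -0.076 (exact permutation p 0.0317, 0.138 after adjustment), by -0.018 in the deeper libraries and by -0.11 in the others. Knockout replicate 5 weighed on this, at 4.52 against 4.66 to 4.71 in the other knockouts. In glutamate transport and in glutamate, glutamine and GABA metabolism the median was above 0 while the mean and the test were below it, and for cyclic nucleotides the reverse held. By fry's test for change in either direction, heme and iron (adjusted p 0.000167) and glutamate transport (adjusted p 0.0336) passed. The 2 heme and iron genes that rose when adjusted over the list alone, Hmox2 and Tfrc, lie on chromosome 16, as Abcc5 does. The glutathione list passed by camera without wildtype replicate 2 (adjusted p 0.0313) and without knockout replicate 3 (adjusted p 0.0144). With an estimated correlation its adjusted p was 0.815 in all libraries and 0.215 without knockout replicate 3.

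**Figure D3:**
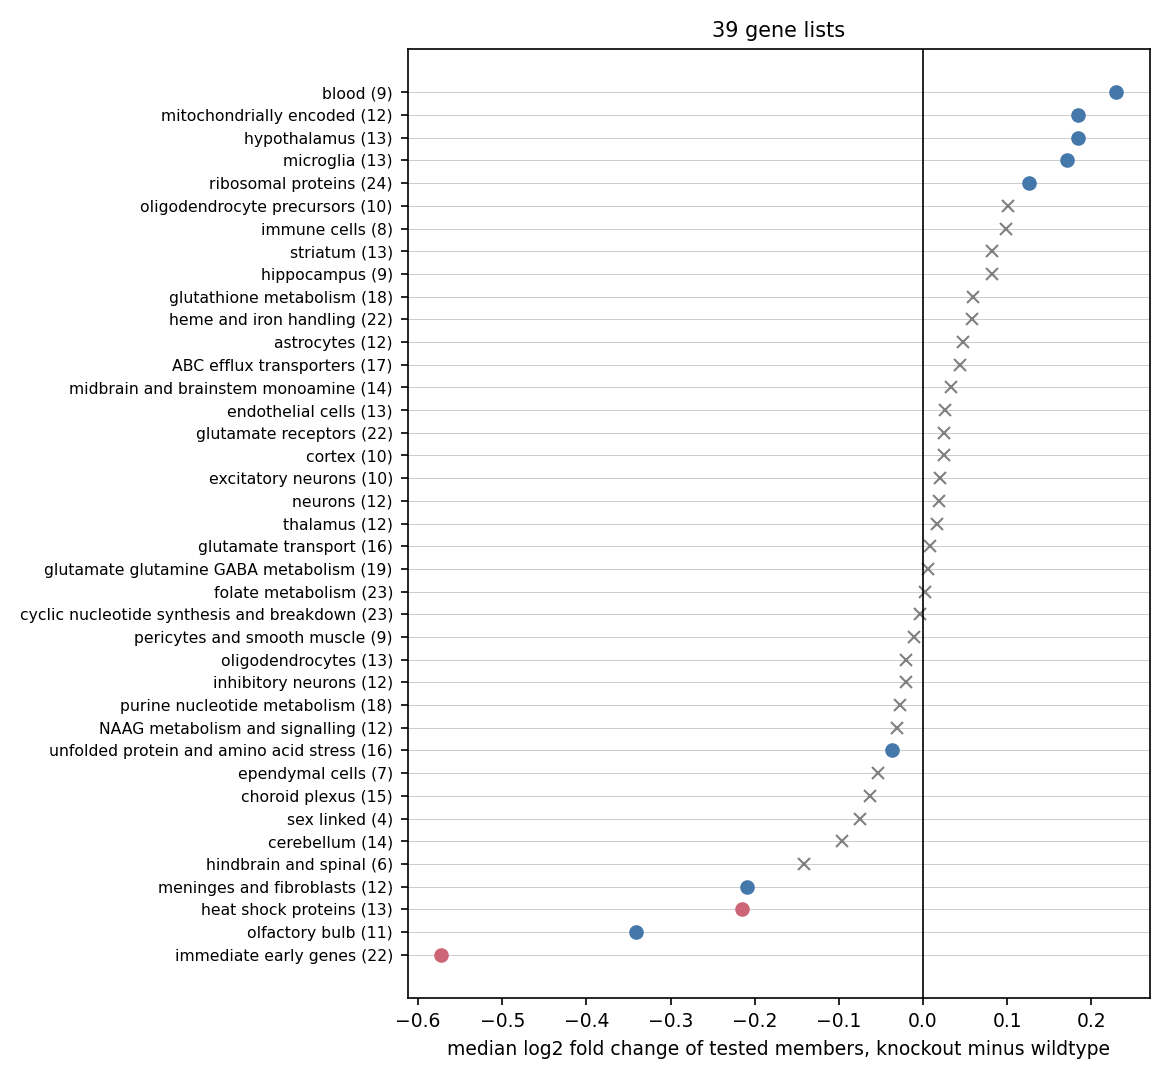
Median log2 fold change (knockout minus wildtype) of the tested members of each of 39 gene lists, with the number of members in parentheses. Red circles passed by camera with both the preset and the estimated correlation, blue circles with the preset one alone, and grey crosses did not pass.

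Marker lists of 14 cell types were compared to see whether the make-up of the tissue differed. The microglial list passed as higher in knockout by camera with the preset correlation. C1qc, a complement component made by microglia, rose from 8.50 ± 0.655 to 12.3 ± 0.967 CPM (n = 5 each, edgeR adjusted p 0.00437), and its partner C1qb had a log2 fold change of 0.34 (edgeR adjusted p 0.0378). Of 13 microglial members 2 rose over all genes and 7 rose when adjusted over the list alone, and the median was 0.17. The camera adjusted p was 8.33e-09, and the adjusted p was 0.0618 with an estimated correlation. The mean log2 CPM of the list differed by 0.22 (exact permutation p 0.00794), by 0.14 in the deeper libraries and by 0.26 in the others. Knockout replicate 3 had the highest score, 4.54, and without it the camera adjusted p was 5.33e-06. The call of C1qb was lost without each library except wildtype replicate 1 and knockout replicate 3, at adjusted p-values from 0.0529 to 0.109, and with the GC trend of each library removed (adjusted p 0.0674). In the 7 shallower libraries alone C1qc had an edgeR adjusted p of 0.0934. P2ry13, a receptor gene of microglia outside the list, had a log2 fold change of 0.49 (edgeR adjusted p 0.0439). Its call was lost without wildtype replicates 1, 2, 3 or 5 or knockout replicates 1, 2 or 5, at 0.0552 to 0.109.

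The lists for meninges and fibroblasts and for blood passed by camera with the preset correlation alone, the first as lower and the second as higher, and not by fry (adjusted p 0.118 and 0.078). By fry's test for change in either direction the adjusted p-values were 0.04 and 0.152. No meningeal gene passed over all genes by edgeR, 5 of 12 were lower when adjusted over the list alone and 5 had an unadjusted p under 0.05, while DESeq2, limma-voom and limma-voom with sample weights called 2, 0 and 1. Col3a1, a fibrillar collagen, and Igf2, a growth factor of the leptomeninges, had log2 fold changes of -0.48 and -0.29, with edgeR adjusted p-values of 0.0522 and 0.0951. The meningeal median was -0.21, with a camera adjusted p of 2.22e-05 and an adjusted p of 0.312 with an estimated correlation. In blood none of 9 genes passed by edgeR, over all genes or when adjusted over the list alone, 2 had an unadjusted p under 0.05, and the same 3 tools called 0, 0 and 1. The blood median was 0.23 (0.10 to 0.28 with 1 library left out), with a camera adjusted p of 0.0166, an adjusted p of 0.181 with an estimated correlation, and a camera adjusted p of 0.0726 without wildtype replicate 4. The mean scores differed by -0.23 for meninges (exact permutation p 0.0714) and 0.19 for blood (exact permutation p 0.0159). They differed by -0.32 and 0.14 in the deeper libraries and by -0.23 and 0.18 in the others.

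The other cell types did not pass by camera, although oligodendrocyte precursors passed by fry's test for change in either direction (adjusted p 0.0423). The medians were 0.019 for neurons, 0.021 for excitatory neurons, -0.020 for inhibitory neurons, 0.048 for astrocytes, -0.020 for oligodendrocytes and 0.10 for their precursors. They were 0.026 for endothelial cells, -0.011 for pericytes and smooth muscle, -0.063 for choroid plexus, -0.053 for ependymal cells and 0.099 for immune cells. With 1 library left out, those of inhibitory neurons, astrocytes, oligodendrocytes, endothelial cells, pericytes, ependymal cells and immune cells changed sign. Neurons then ran from 0.0071 to 0.034, excitatory neurons from 0.012 to 0.11, precursors from 0.034 to 0.17 and choroid plexus from -0.10 to -0.015. No gene of these lists passed over all genes by edgeR, and 2 precursor genes rose when adjusted over the list alone. Olig1 and Olig2, transcription factors of the oligodendrocyte lineage, had log2 fold changes of 0.22 and 0.34, with edgeR adjusted p-values of 0.0796 and 0.179. Over all 14 lists DESeq2 called 7 genes, limma-voom 2 and limma-voom with sample weights 8, with 24 of 155 at an unadjusted edgeR p under 0.05. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, had a log2 fold change of 0.077. For inhibitory neurons the median and mean were below 0 while the test pointed upward. The oligodendrocyte list passed as lower in the 7 shallower libraries alone (median -0.090, camera adjusted p 0.017). The precursor list passed by camera without knockout replicate 5 (adjusted p 0.0177). Pomc, a pituitary marker, had a log2 fold change of 0.57 (edgeR adjusted p 0.293), and Sag, of the pineal and retina, had 0.31 (edgeR adjusted p 0.52). With 1 library left out these ran from 0.41 to 0.91 and from 0.17 to 0.44. The sex-linked list had a median of -0.075 and passed by camera without wildtype replicate 4 (adjusted p 0.0354).

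Lists of brain regions were compared because dissection can vary the share of each region. Knockout replicate 3 differed from every other library in cerebellar transcripts. Cbln3, a secreted protein of cerebellar granule cells, had 2.51 CPM in this library (19 counts) and 307 ± 33.8 CPM in the other 9, so that it reached 0.817% of their mean (95% exact Poisson interval 0.491 to 1.27%, counting error only). Gabra6, the granule cell GABA receptor subunit, and Pcp2, a Purkinje cell gene, reached 0.965% and 1.44%. Gabra6, Pcp2 and Car8, a further Purkinje cell gene in the plot of cerebellar genes, were chosen after their values were seen. The cerebellum list had a median of -0.096 (camera adjusted p 0.0706) over all 10 libraries. Without knockout replicate 3 the direction turned, with a median of 0.091 and a camera adjusted p of 0.00115, and an adjusted p of 0.433 with an estimated correlation. Without knockout replicates 1, 2, 4 or 5 the list passed as lower (camera adjusted p 0.0091, 0.00378, 0.00465 and 0.0497). Markers of the hindbrain and spinal cord had a median of -0.14 and passed as lower without knockout replicates 2 or 4 (camera adjusted p 0.00868 and 0.0104). Without knockout replicate 3 this median turned too, to 0.18 (camera adjusted p 0.44). The low-count filter was run anew without that library, which left 8 tested members against 6 over all libraries. In the 7 shallower libraries, which include knockout replicate 3, both lists passed as lower, with medians of -0.38 and -0.74 (camera adjusted p 0.000129 and 0.000142).

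**Figure D4:**
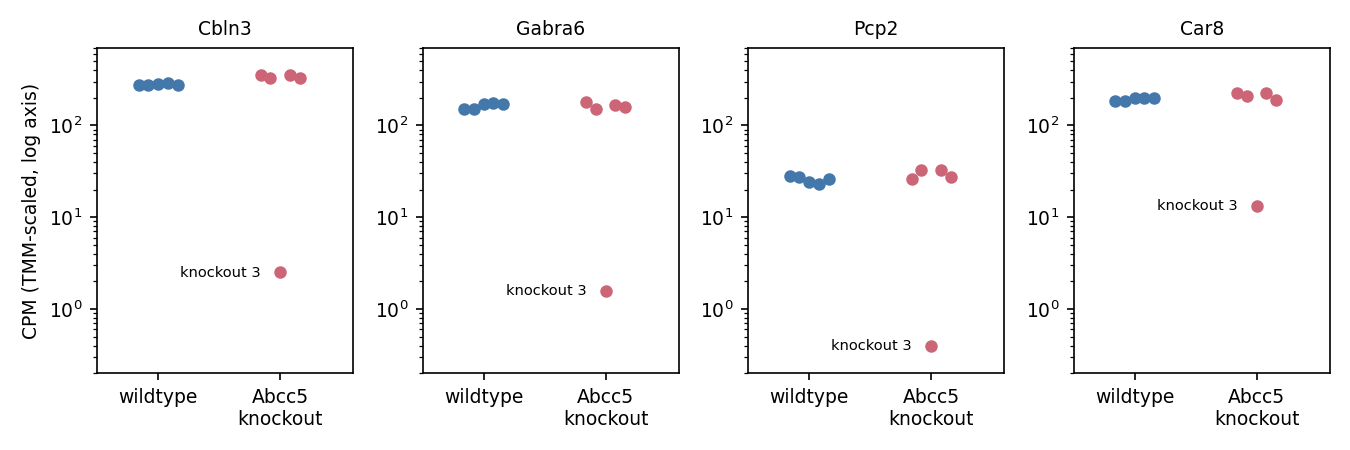
Level (CPM, log axis) of 4 cerebellar genes in each wildtype and knockout library (points). Knockout replicate 3 lies far below the other 9 libraries in each panel, at 2.51 CPM for Cbln3.

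Among the other regions, the lists for the olfactory bulb and the hypothalamus passed by camera with the preset correlation, the first as lower and the second as higher. Eomes, a transcription factor of olfactory bulb projection neurons, fell from 16.0 ± 1.44 to 7.09 ± 3.43 CPM (n = 5 each, edgeR adjusted p 0.00805) and was the single call of 11, also when adjusted over the list alone. The olfactory bulb median was -0.34 (-0.44 to -0.19 with 1 library left out), with a camera adjusted p of 0.00173, an adjusted p of 0.663 with an estimated correlation and 0.356 by fry. Its mean log2 CPM was low in knockout replicates 1 and 2 alone (3.04 and 3.24), and the exact permutation p was 0.119. In the 7 shallower libraries alone the camera adjusted p was 0.0567, and that of Eomes by edgeR was 0.144. Avp, the vasopressin gene, rose from 5.64 ± 0.844 to 8.65 ± 0.553 CPM (edgeR adjusted p 0.0233) and was the single hypothalamic call of 13, with 2 when adjusted over the list alone. Its call was lost without wildtype replicates 2, 3, 4 or 5 or knockout replicates 1 or 4, at 0.0528 to 0.0799. The hypothalamus median was 0.18, with a camera adjusted p of 0.00403 and an adjusted p of 0.181 with an estimated correlation. Its mean log2 CPM differed by 0.22 (exact permutation p 0.00794). Without knockout replicate 3, which had the highest score, the median was 0.087 (14 tested members) and the camera adjusted p 0.0679. The olfactory bulb and hypothalamus differed by -0.71 and 0.086 in the deeper libraries and by -0.34 and 0.27 in the others.

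The remaining regions did not pass by camera. Their medians were 0.025 for cortex, 0.082 for hippocampus, 0.082 for striatum, 0.017 for thalamus and 0.034 for the monoamine nuclei of the midbrain and brainstem. With 1 library left out they ran from -0.065 to 0.083, 0.022 to 0.11, 0.015 to 0.14, 0.010 to 0.050 and 0.020 to 0.049, and that of cortex was lowest without knockout replicate 3. In the last list Nr4a2, also an immediate early gene, was the single call, and that list passed by fry's test for change in either direction (adjusted p 0.00954). Adjusted over the list alone, 1 gene was lower in each of cortex, hippocampus, thalamus and the monoamine nuclei, namely Egr3, Prox1, Rgs16 and Nr4a2. Egr3, Prox1 and Rgs16 had log2 fold changes of -0.44, -0.18 and -0.27 and edgeR adjusted p-values of 0.0957, 0.129 and 0.094. In cortex the mean and test were below 0 against a median above it, and in thalamus the mean alone was below 0. Over all 9 region lists edgeR called 3 of 102 genes, with 12 at an unadjusted p under 0.05, and DESeq2, limma-voom and limma-voom with sample weights called 4, 3 and 6. The striatum list passed by camera as higher without knockout replicate 4 (adjusted p 2.86e-05) and in the 7 shallower libraries alone (median 0.15, adjusted p 0.000124).

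A gene disrupted in stem cells of another strain can carry flanking DNA of that strain, so calls near Abcc5 were counted. Within 10 Mb, 2 of 158 other tested genes passed, both lower in knockout. Snx29, a sorting nexin, fell from 10.98 ± 0.912 to 7.03 ± 0.487 CPM (n = 5 each, edgeR adjusted p 0.00175). Map3k13, a kinase of the JNK pathway, fell from 47.8 ± 3.77 to 36.8 ± 5.14 CPM (edgeR adjusted p 0.0362). In the 7 shallower libraries alone neither passed (edgeR adjusted p 0.0543 and 0.291). Elsewhere 168 of 14367 genes passed. No difference in shares was found (two-sided Fisher's exact p 0.709), although the test rested on only 2 calls near Abcc5. Emp2, with the smallest p of all tested genes, lay just outside, 10.05 Mb from Abcc5. Alg1, with the smallest p of the raised genes, lay 15.1 Mb away. Alg1, Emp2 and Snx29 lay on the same side of Abcc5, and Map3k13 on the other. Within 20 Mb there were 6 calls of 289 (Fisher's exact p 0.156). On chromosome 16 there were 8 calls of 458 (Fisher's exact p 0.262). Map3k13 lost its call without wildtype replicates 1, 3, 4 or 5 or knockout replicates 1, 2 or 4, at edgeR adjusted p-values of 0.0649 to 0.106. The number within 10 Mb was 1 without wildtype replicates 1, 3, 4 or 5 or knockout replicates 1, 2 or 4, 4 without knockout replicate 5, and 5 without knockout replicate 3.

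**Figure D5:**
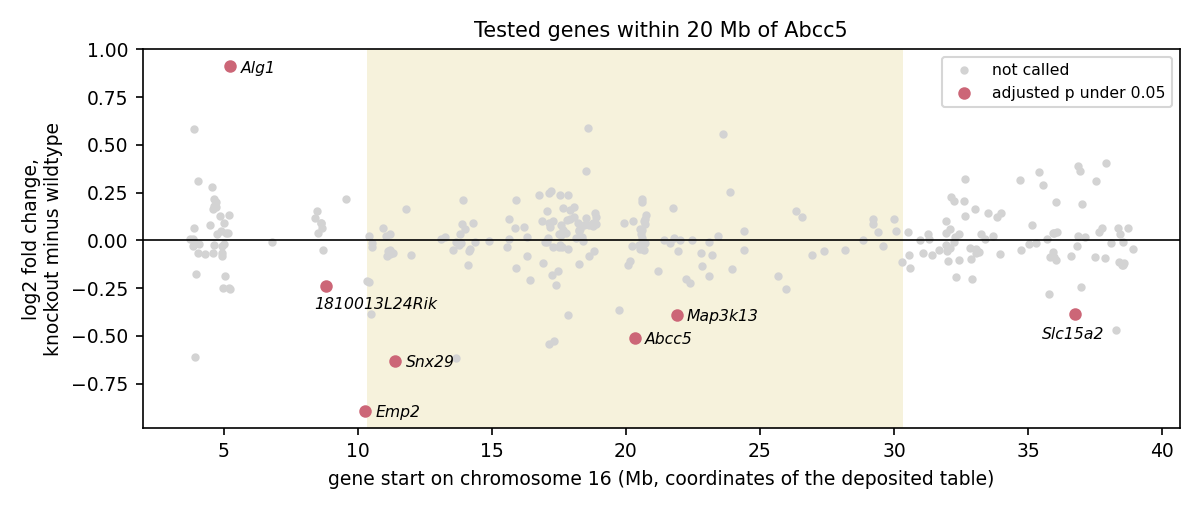
Log2 fold change (knockout minus wildtype) of tested genes within 20 Mb of Abcc5 by start position on chromosome 16 (Mb). Red points have an edgeR adjusted p under 0.05, and the shaded band marks 10 Mb to either side of Abcc5, where 2 genes besides Abcc5 passed.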

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

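In the groups of 5 libraries, 164 sets of values were searched for a library far from the rest, and 12 were found where chance gives about 8.2, with 6 of them in knockout replicate 3. Of the tests below, those for transcript length and an effect of the genotype on the cerebellum were chosen only after the result was seen, as were the criterion by which the planned Fisher's test was read for flanking DNA, the use of the 7 shallower libraries alone and the windows of 5 and 20 Mb with the threshold of 0.01 or without knockout replicate 3.

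Immediate early genes were lower in knockout, with a median log2 fold change of -0.57. Fewer excitatory neurons are argued against by their markers (median 0.021, quartiles -0.0097 to 0.13). A single library is argued against by the list median, -0.64 to -0.50 with 1 library left out. The list scores also did not overlap, with at least 5.37 in wildtype and at most 5.07 in knockout. The planned measure, the highest camera adjusted p with 1 library left out, was 1.82e-47. Its size rests on the preset correlation of 0.01, where 0.361 was estimated. Sequencing depth is argued against by the median of -0.41 in the 7 shallower libraries. Another time of day at collection may contribute and stays open. Of 11 clock genes, 3 (Hlf, Npas2 and Cry1) had an unadjusted edgeR p under 0.05. Over all tested genes, 2145 of 14526 had such an unadjusted p. The 11 were chosen outside the calls already seen, so that none of them passed adjustment was set by this choice. Per1, a clock component that was called (log2 fold change -0.62, edgeR adjusted p 0.00128), was not among them. Arntl, Npas2 and Clock were predicted to go against Dbp, Per3, Nr1d1, Tef and Ciart. Only Npas2 did (0.21, against 4 of those 5 below 0), with -0.026 for Arntl and -0.042 for Clock. An effect of the genotype stays open too, and was not tested apart from collection, since the time and order of collection are not given in the sources used here.

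Calls near Abcc5 were 2 within 10 Mb. Flanking DNA of the strain in which the gene was targeted may account for some of them, and the Fisher's exact p of 0.709 leaves this open, since few genes were called and the length of any flanking segment is not given in the sources used here. Within 5, 10 and 20 Mb the p was 1, 0.709 and 0.156, at the stricter threshold of 0.01 it was 1, 0.493 and 0.0348 (for 20 Mb 4 of 289 against 58 of 14236), and without knockout replicate 3 it was 0.325, 0.420 and 0.0469. An effect of the genotype on these genes was not tested apart from this.

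Knockout replicate 3 had a cerebellar score of 3.63, against 6.58 to 6.80 in the other knockouts, and a hindbrain score of -0.83, against 1.86 to 2.85. Transcript length bias is argued against by 179 genes matched in length to the 20 genes over 8-fold lower, whose median deviation was 0.062 (quartiles -0.098 to 0.17) against -4.23. A lowering of cerebellar transcripts by the genotype is argued against by 0 of the other 4 knockout libraries scoring below all wildtype libraries. The test did not cover a rise. Knockout replicates 1, 2 and 4 scored 6.755, 6.795 and 6.779, against at most 6.675 in wildtype, and knockout replicate 5 scored 6.578. Dissection of another share of brain regions is a candidate explanation, since the lowest median deviation of a region list was -3.55 (hindbrain) and cortex and striatum deviated by 0.40 and 0.38. Region scores of other knockouts also left the wildtype range. Olfactory bulb was 3.041 and 3.235 in knockout replicates 1 and 2 (wildtype 4.002 to 4.335). Cortex and striatum were 5.661 and 5.379 in knockout replicate 4 (wildtype at least 5.846 and 5.618). Thalamus and monoamine scores stayed within the wildtype range in every knockout.

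In the same library the folate score was 3.55 (others 3.75 to 3.83), the glutathione score 4.89 (5.02 to 5.06), the microglia score 4.54 (4.33 to 4.37) and the hypothalamus score 3.17 (2.86 to 2.93), in log2 CPM. The NAAG score of knockout replicate 5 was 4.52 (others 4.66 to 4.71), and the neuron score of wildtype replicate 1 was 8.97 (8.94 to 8.95). Egr2 was 3.32 in wildtype replicate 4 (others 3.67 to 3.74), and Avp was 2.97 in knockout replicate 2 (3.14 to 3.2). In wildtype replicate 2, Slc38a2 was 7.76 (others 7.96 to 8.00) and Map3k13 was 5.37 (5.59 to 5.66).

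Other groupings of the libraries were examined with 100 of the 126 possible splits. For genes, 1 of 100 splits, the real one, gave as many as 171, and the highest other gave 0. Other splits mix the genotypes within a group, which widens its spread and lowers their counts. With 126 possible splits, this makes chance unlikely as the source of the count but cannot exclude it. For lists, 42 of 100 gave as many as 10, and the highest other gave 18, so chance cannot be excluded for the number of lists called with the preset correlation.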

How the results depend on the processing

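The tests on the 7 shallower libraries, with depth class as a term and with the GC trend removed were chosen only after the data were seen. The Abcc5 log2 fold change kept its direction and its call in every alternative run on it, with -0.53 to -0.49 when 1 library was left out. The number of genes past the threshold ranged from 76 to 341 with 1 library left out. It was 90 with the replicate number as a block (86 shared), although correlations between equal numbers did not mark them as pairs. It was 563 by limma-voom with sample weights, 259 by the DESeq2 Wald test, 63 and 373 at adjusted p thresholds of 0.01 and 0.1, 26 against a 1.2-fold change, 31 in the 7 shallower libraries (30 shared) and 281 with the GC trend removed (157 shared). Fewer samples and the thresholds' own construction account for some of these, and for the other alternatives the cause was not tested. Of 41 named called genes, 15 kept direction and side of the threshold in all 21 alternatives, and 0 reversed. The number of lists called was 2 with an estimated correlation and 6 by fry, and 10 to 13 with 1 library left out. Fry called the immediate early, heat shock, unfolded protein, ribosomal, microglial and hypothalamic lists, and its test for change in either direction called 11. Calls near Abcc5 by edgeR were 0 in the 7 shallower libraries, where Snx29 and Map3k13 had adjusted p-values of 0.0543 and 0.291, and 1 to 5 with 1 library left out. Without knockout replicate 3, Cbln3 turned to a log2 fold change of 0.29 (edgeR adjusted p 0.000299, range -0.13 to 0.29 with 1 library left out). The cerebellum list turned to a median of 0.091 (camera adjusted p 0.00115, range -0.20 to 0.091). The values below 0 over all libraries follow from that library's low cerebellar counts, which do not account for the rise without it. In the other knockouts Cbln3 had 329.2 to 353.9 CPM, against 272 to 287.5 CPM in wildtype, and the cause was not tested. In the 7 libraries the olfactory bulb list did not pass (camera adjusted p 0.0567), while the cerebellum (0.000129), hindbrain (0.000142) and oligodendrocyte lists (0.017) passed as lower and the striatum list as higher (0.000124). The cerebellum and hindbrain lists also passed as lower with the replicate number as a block (camera adjusted p 0.00791 and 0.0165) and with depth class as a term (0.00977 and 0.0259). The cerebellum list did so with upper-quartile scaling (0.0267) and without the low-count filter (0.00811) too. The sex covariate was not run, since all libraries had Y-linked counts. With 7731294 counts in the smallest library, differences in genes of about 1 CPM rest on few counts.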

Other observations

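The test of body temperature was written before its result was seen, while the GC trend and olfactory bulb values below were examined only after the data were seen. Clock genes chosen outside the calls already seen had small differences, and Per1, which was called, was not among them. Cry1, a repressor of the clock, had a log2 fold change of -0.29 (edgeR adjusted p 0.131), Hlf had -0.13 (edgeR adjusted p 0.248) and Npas2 had 0.21 (edgeR adjusted p 0.281). Dbp, a clock output gene with wide daily swings, had 0.013 (SE 0.081).

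Heat shock genes were lower and Cirbp, which cold induces, was higher in knockout, so lower body temperature at collection was tested as a hypothesis. Rbm3, another cold-induced gene, had a log2 fold change of -0.073 (SE 0.062, edgeR adjusted p 0.625), which argues against it.

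The olfactory bulb gene Eomes had 4.63, 3.64, 7.12, 7.58 and 12.5 CPM in knockout replicates 1 to 5 and 14.7 to 18.0 CPM in wildtype. Across genes, which are not independent replicates, the deviation of a library had a Spearman rho with transcript GC of 0.694 in wildtype replicate 1 and of 0.425 and 0.430 in knockout replicates 2 and 4, the 3 deeper libraries. The log2 fold change had a rho with GC of 0.243 over genes with a GC value, and of -0.0070 after the trend was removed.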
